A study of Homo sapiens with 6 samples.

How the data were processed

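RNA was measured in cells of Huh1 and Huh7, human hepatocellular carcinoma lines, that the labels describe as negative for the surface protein EpCAM. Cells of each line were left as controls or treated for 48 h with disulfiram at 0.1 uM, an aldehyde dehydrogenase inhibitor, or with 5-fluorouracil (5-FU) at 1 uM, a pyrimidine analogue that blocks thymidylate synthase. There were 6 single-colour Agilent arrays, 1 for each line and treatment, so each treatment had 2 arrays, 1 per line, and each line had 3. No separate replicate cultures were hybridised. The p-values below therefore rest on how far the treatments' differences disagreed between the lines and on array variation, not on repeated cultures. A drug response specific to 1 line adds to that spread.

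The deposited scanner files hold intensities made by the authors with Agilent Feature Extraction 10.7.1.1: the processed signal, background-subtracted and detrended within the array, and the median pixel intensities of each spot and its local background. The table of values deposited by the authors holds a ratio, each probe's mean processed signal divided by the array's 75th percentile. Checked against the scanner files, the 75th percentile of that table equalled 1 on each array and its medians lay between 0.089 and 0.114. After removal of 1 constant per array the probe means deviated by a relative median absolute deviation of at most 0.00876%.

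Each array had 43118 non-control spots and 34127 probes. Spots marked as outliers by the scanner software were left out, and the spots of a probe were averaged. The processed signal was put on the log2 scale and each array's 75th percentile was subtracted. All levels below are on this scale. A probe name was matched to the reference gene table for 25771 probes, and 8356 probes had no name there and were left out of the gene-level test. A probe was kept if it was well above background on at least 2 of the 6 arrays, and each gene was represented by its kept probe with the highest mean over all arrays. This gave 14683 genes.

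Depth was judged from signal over background. Between 20252 and 21910 probes were above background on an array, and the array's 75th percentile lay between 1293 and 2233 intensity units. The 999 probes printed 10 times had a median log2 SD between 0.034 and 0.0629, which set the noise of a log2 ratio within an array pair at 0.13. This covers the spot noise alone. The number of arrays limits the precision of every comparison.

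Genes were tested with limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8) for reading files. The model had the treatment and the cell line as terms, which left 2 residual degrees of freedom, and the empirical Bayes prior added 2.49. The comparisons were disulfiram against control, 5-FU against control, disulfiram against 5-FU, and Huh7 against Huh1 over the 3 treatments. All limma tests were two-sided. Genes passed at a Benjamini-Hochberg adjusted p below 0.05. Errors after ± are limma standard errors.

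Before the data were examined, 34 lists of pathways, complexes and cell type markers were fixed, together with the comparisons, the tests, the alternatives and the rule for naming genes. Of their 1013 entries, 1007 were matched to a reference gene. Endothelial markers had fewer than 5 tested members and were not tested, which left 33 lists. Each list was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The estimated form also tests on the 2 residual degrees of freedom, so it could hardly pass any list here. Cholangiocyte markers had an estimate of -0.036, below the preset, yet with 5-FU their unadjusted camera p was 0.068 with it and 0.000738 with the preset. Other estimates reached 0.787 (DNA replication), far above the preset. Neither form settles whether a list moved. A list's value is the median log2 fold change of its tested members. Counts of members past the threshold were taken over all genes tested and adjusted over the list alone.

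Genes named below followed 3 rules. In each direction of a comparison, the 10 genes with the largest change among those past the threshold were eligible if they had the same sign in both lines or in all 3 treatments. Free places went to the genes whose smaller change among the lines was largest, given as values. From each list, up to 4 members with the largest absolute change were eligible, of which the leading ones are given, and 10 further genes were given in every array. Not all eligible genes are printed, for length. For some eligible genes another probe had the opposite sign in a comparison, so a gene's value holds for the probe chosen. Where every array of a group was below background, a fold was computed against the background level and is given as at least that size.

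The correlation of the drug responses was set beside 100 simulations of unchanged groups against shared controls. Random rotations of the data, 100 in all, kept the correlation between genes and the cell line term and turned the remaining differences between arrays in random directions. Rotations of the measured data still gave many lists past the camera threshold. The median was 14 lists for disulfiram (7 to 21) and 13 for 5-FU (5 to 22). With a drug effect planted alike in both lines, at a log2 change of 3 in 20 lists of rotated data, 62 of 100 rotations for disulfiram and 66 for 5-FU still gave as many lists. With 5 added to the measured disulfiram values of the 9 metallothioneins, on top of their observed difference, 7 gave as many calls. Rotations therefore could not tell a drug effect from its absence in this design, and no result rests on them. They were added after the numbers of lists past the threshold had been seen, and for the metallothioneins the bound was set before the rotations were run. The planted effects came after both.

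The pipeline was tested on simulated data with the real gene means and the moderated limma spreads, each gene drawn independently. Such spreads are more alike than the measured ones, so the shares below can be too high for the real arrays. In the measured data MT1G, at 6.51 for disulfiram against control, had a limma adjusted p of 0.906. Among 200 genes changed by disulfiram, 0% passed at a log2 change of 1, 78% at 2 and 98% at 3, with 0, 12 and 15 calls among unchanged genes. For Huh7 against Huh1, 0%, 91.5% and 97.5% passed, with 0, 17 and 19 such calls. All 10 of 10 lists shifted by 0.5 passed and 0 of 23 other lists did, with genes simulated as independent.

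Alternatives changed the background correction, the normalization (quantile, median centring, the authors' table), the filter on dim probes, the choice of probe, outlier spots, the prior variance, the cell line and slide terms and the estimated correlation. Each array was left out in turn, and each line for fold changes. The correction by normexp with an offset of 50 was run on the median spot signals, because the files hold no mean signals. Cyclic loess between arrays and a test of each probe, unnamed ones included, were added after seeing the data. The Huh1 control and Huh1 disulfiram arrays were on slide 1, and the other 4 arrays were on slide 2.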

Results

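Gene expression was measured in cells of Huh1 and Huh7, labelled as EpCAM-negative, left untreated or treated for 48 h with disulfiram at 0.1 uM or 5-FU at 1 uM, with 1 array for each line and treatment. EpCAM is a surface protein carried by tumour-initiating hepatocellular carcinoma cells, and the labels describe the cells as non-tumor-initiating. Of 34127 probes, 20252 were above background in Huh1 control, 21910 in Huh1 5-FU and 20686 in Huh1 disulfiram. The counts were 20906 in Huh7 control, 21230 in Huh7 5-FU and 21700 in Huh7 disulfiram. The cell line was the main difference between the arrays: the first principal component held 84.8% of the variance and separated Huh1 from Huh7. Across 14683 genes, which are not independent replicates, Pearson's r lay between 0.961 and 0.986 for arrays of a line and between 0.770 and 0.794 for arrays of different lines.

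Disulfiram, whose metabolite binds copper, was compared with the controls to ask which genes differed in cells exposed to it. The metallothioneins, small proteins that bind zinc and copper, were far higher in the disulfiram arrays of both lines. MT1G (gene 4495, chromosome 16) had a log2 fold change of 6.51 ± 1.03, a 91.3-fold difference, with 5.65 in Huh1 and 7.37 in Huh7. MT1M (58.3-fold), MT1E (38.7-fold), MT1L (32.2-fold), MT1B (31.2-fold), MT1H (30.3-fold), MT1X (25.8-fold), MT1F (24.5-fold) and MT1A (7.57-fold) lay on the same side in both lines. The median over these 9 genes was 4.42 in Huh1, a 21.5-fold difference, and 5.70 in Huh7, a 52.1-fold difference, and within each line the disulfiram and control arrays shared a slide. Among other members of that list SLC30A1, a zinc exporter, had 0.80 ± 0.69, with 0.18 in Huh1 and 1.42 in Huh7, and ATP7B, a copper exporter, had -0.36 ± 0.30.

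All 9 metallothioneins passed when adjusted over the list alone, with adjusted p between 0.00328 for MT1A and 0.0398 for MT1F, while 0 passed over all genes tested (limma adjusted p = 0.906 for each). The copies are close in sequence, so their probes are not independent measurements of 9 transcripts. The list of metallothioneins and metal transporters, 22 tested members, had a median of 0.39 (0.11 in Huh1 and 0.90 in Huh7) and passed camera (adjusted p = 7.1e-07, and adjusted p = 0.766 with an estimated correlation).

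**Figure D1:**
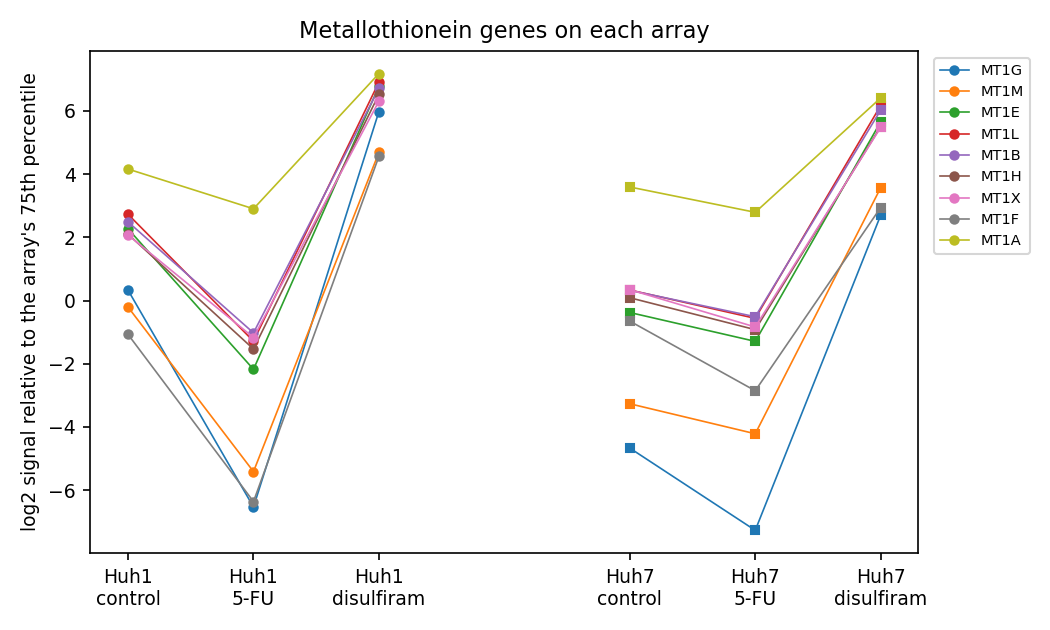
The level of 9 metallothionein genes on each of the 6 arrays, as log2 signal relative to the array's 75th percentile. Circles are Huh1 arrays, squares are Huh7 arrays, and lines join the arrays of a gene within a line. The median log2 ratio of disulfiram over control was 4.42 in Huh1 and 5.70 in Huh7, and that of 5-FU over control was -4.02 and -0.95.

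Genes of inflammation and stress were higher with disulfiram, with larger values in Huh7 than in Huh1, a difference that was not tested. NF-kappaB target genes rose as a list (median 0.95, adjusted p = 7.1e-07, and adjusted p = 0.766 with an estimated correlation, as for each list of this paragraph), with medians of 0.05 in Huh1 and 1.92 in Huh7, and the median was 0.65 with genes below background at their bound. CXCL8, a neutrophil chemokine, had 2.79 ± 0.66. TNF, an inflammatory cytokine that was below background in both controls, was at least 1.58-fold higher, and it was below background on the Huh1 disulfiram array as well, so the bound rests on Huh7. Below-background groups are given such a lower bound because the true level is unknown. Genes of endoplasmic reticulum stress and the integrated stress response rose (median 0.40, adjusted p = 0.000423; 0.04 in Huh1 and 0.55 in Huh7). Its leading member ATF3, a stress-induced transcription factor, had 2.46 ± 0.76, and PPP1R15A, which restores translation after stress, had 1.66 ± 0.63. Genes of glycolysis and the hypoxia response rose (median 0.46, adjusted p = 0.0002), with medians of -0.06 in Huh1 and 1.05 in Huh7. CA9, a hypoxia-induced carbonic anhydrase, had 2.70 in Huh1 and 2.98 in Huh7, while ENO2, a glycolytic enzyme, had -0.25 and 3.97. The list of immediate early genes and the p38 pathway rose (median 0.35, adjusted p = 0.0264; -0.08 in Huh1 and 0.53 in Huh7), led by FOSB, an AP-1 subunit, at 1.81 ± 0.42. KLF4, a transcription factor, had -0.05 in Huh1 and 2.81 in Huh7. Interferon-stimulated genes rose (median 0.29, adjusted p = 0.0264; -0.02 in Huh1 and 0.60 in Huh7), with IRF7, a regulator of interferon genes, at 1.98 ± 0.89 and ISG20, an exonuclease, at 1.06 ± 0.57. Hepatocyte genes (median 0.26, adjusted p = 0.00415; 0.20 in Huh1 and 0.16 in Huh7) also rose, and so did cholangiocyte markers, genes of bile duct cells, over both lines (median 0.30, adjusted p = 0.0399), with -0.04 in Huh1 and 0.30 in Huh7. HPD, a tyrosine-degrading enzyme, had 2.65 ± 1.07, and TFF3, a trefoil peptide, had 1.24 ± 0.31. On 1 of the 2 control arrays CXCL8, CA9, KLF4, IRF7 and HPD were below background, so their sizes rest in part on levels at background.

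Genes of proliferation and of the basic machinery of the cell were lower with disulfiram. DNA replication genes fell (median -0.45, adjusted p = 7.1e-07, and adjusted p = 0.766 with an estimated correlation, as for each list of this paragraph), and 34 of 35 members had a value below 0, but the medians were -0.08 in Huh1 and -0.84 in Huh7. GINS2, part of the replicative helicase, had -0.70 ± 0.29, and UHRF1, which maintains DNA methylation at replication, had -0.67 ± 0.32. Oxidative phosphorylation genes fell in both lines by a similar size (median -0.27, adjusted p = 1.6e-06; -0.32 in Huh1 and -0.24 in Huh7), with all 34 members below 0, among them NDUFC2, a complex I subunit, at -0.45 ± 0.23. Random lists of genes as bright as these had a median of -0.18 (middle 95% -0.25 to -0.10), so bright genes in general fell as well. The proteasome list fell (median -0.22, adjusted p = 1.69e-05; -0.30 in Huh1 and -0.20 in Huh7) with all 31 members below 0, led by PSMD3, a subunit of its regulatory particle, at -0.44 ± 0.19. The pyrimidine and folate list (median -0.19, adjusted p = 0.00241; -0.11 in Huh1 and -0.34 in Huh7), ribosome biogenesis (median -0.24, adjusted p = 0.00305; -0.07 in Huh1 and -0.36 in Huh7) and ribosomal proteins (median -0.16, adjusted p = 0.00241) fell as well, though ribosomal proteins had 0.04 with loess between arrays and in Huh7 0.03. The medians of the proteasome, the pyrimidine and folate list, ribosomal proteins and mitosis lay within the middle 95% of random lists of matched brightness. UNG, a uracil-DNA glycosylase, had -0.69 ± 0.22, BOP1, a ribosome assembly factor, had -0.59 ± 0.35, and RPL22, a ribosomal protein, had -0.46 ± 0.27. The mitosis list fell (median -0.18, adjusted p = 0.0433), with medians of 0.33 in Huh1 and -0.70 in Huh7, and its leading member PLK1, a mitotic kinase, had 0.02 and -0.95. Replication-dependent histones fell (median -0.25, adjusted p = 0.0433; 0.09 in Huh1 and -0.61 in Huh7), with H2AC20 at -0.56 ± 0.26 and H3C10 at -0.46 ± 0.33.

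Some further lists fixed in advance did not pass, and RNA levels do not measure whether disulfiram inhibited a protein. Aldehyde dehydrogenases had a median of -0.05 (adjusted p = 0.468), and the p97 and NPL4 pathway, which extracts ubiquitinated proteins, had -0.06 (adjusted p = 0.399). Tumour-initiating and hepatic progenitor markers had -0.09 (adjusted p = 0.327), and p53 target genes had 0.04 (adjusted p = 0.468). MMP1, a collagenase below background in both controls, was at least 13.8-fold higher in the disulfiram arrays. LINC00892, a non-coding RNA, was at least 3.34-fold lower.

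Of 14683 genes, 0 passed in limma between disulfiram and control (lowest adjusted p = 0.906), and 576 had an unadjusted p below 0.05, against 734 expected by chance. Of the 33 lists tested, 16 passed, 8 higher and 8 lower, and 0 passed with an estimated correlation (adjusted p = 0.766 for each list named above as risen or fallen). The count over the 33 lists was 10 with quantile normalization, of which 8 were among the 16. It was lower still without the Huh7 control array, which left 1 control array.

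5-FU was compared with the controls to ask which genes differed in cells exposed to a pyrimidine analogue. NF-kappaB target genes were the list with the largest median shift: it was 1.52 (adjusted p = 2.43e-08, and adjusted p = 0.837 with an estimated correlation, as for each list of this paragraph), 2.02 in Huh1 and 1.15 in Huh7, and 1.104 with genes below background at their bound, with CXCL8 at 3.49 ± 0.66 and TNF at least 4.85-fold higher. p53 target genes, which arrest the cycle and respond to DNA damage, rose (median 0.40, adjusted p = 0.00121) with 0.40 in both Huh1 and Huh7. GDF15, a stress-induced cytokine, had 3.49 ± 0.66, an 11.3-fold difference, and CDKN1A, an inhibitor of cyclin-dependent kinases, had 2.50 ± 0.69. Ribosomal proteins fell (median -0.54, adjusted p = 3.02e-11), with 37 of 38 members below 0 in both lines and RPL3, a ribosomal protein, at -1.23 ± 0.22. Random lists of genes as bright as the ribosomal proteins had a median of -0.39, so much of this fall was shared by bright genes in general. Replication-dependent histones, which package newly made DNA, fell (median -0.88, adjusted p = 2.43e-08, and -0.85 with genes below background at their bound), with all 20 members below 0 and H1-2, a linker histone, at -1.18 ± 0.27.

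Other lists of signalling and liver function were higher with 5-FU. With an estimated correlation the adjusted p lay between 0.837 and 0.852 for the lists of this paragraph. Hepatocyte genes rose (median 0.86, adjusted p = 5.43e-09; 0.42 in Huh1 and 1.16 in Huh7), with HPX, a haem carrier, at 2.41 ± 0.39, and 8 of 38 members passed when adjusted over the list alone, against 0 over all genes tested. The immediate early list rose (median 0.66, adjusted p = 0.000991; 0.61 in Huh1 and 0.68 in Huh7), with JUN, an AP-1 subunit, at 2.18 ± 0.22 and FOSB at 2.41 ± 0.42. The list of xenobiotic metabolism and drug transport rose (median 0.73, adjusted p = 0.000991; 0.26 in Huh1 and 1.102 in Huh7). ABCB1, a drug efflux pump, had 2.40 ± 0.20 and an adjusted p of 0.00351 over its list alone, with 2.30 in Huh1 and 2.50 in Huh7. Interferon-stimulated genes rose (median 0.65, adjusted p = 0.000991; 0.01 in Huh1 and 1.19 in Huh7, and 0.55 with genes below background at their bound), with IRF7 at 2.90 ± 0.89. Cholangiocyte markers rose (median 0.58, adjusted p = 0.00203; 0.48 in Huh1 and 0.52 in Huh7), with TFF3 at 2.48 ± 0.31. Apoptosis regulators (median 0.29, adjusted p = 0.00203; 0.11 in Huh1 and 0.33 in Huh7) and cholesterol biosynthesis (median 0.26, adjusted p = 0.0152; 0.03 in Huh1 and 0.21 in Huh7) rose, with ACAT2, which makes acetoacetyl-CoA, at 0.78 ± 0.31. The list of epithelial-mesenchymal transition and TGF-beta targets rose (median 0.19, adjusted p = 0.00731), with 0.54 in Huh1 and -0.03 in Huh7. TGFB2, a growth factor, had 5.01 in Huh1 and -0.58 in Huh7. On 1 of the 2 control arrays CXCL8, HPX, IRF7 and TGFB2 were below background, so their sizes with 5-FU rest in part on levels at background.

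Lists of protein turnover and growth were lower with 5-FU, with an adjusted p between 0.837 and 0.904 with an estimated correlation. The proteasome fell (median -0.43, adjusted p = 1.64e-06; -0.35 in Huh1 and -0.50 in Huh7), with 30 of 31 members below 0 and PSMA3, a core subunit, at -0.86 ± 0.27. Oxidative phosphorylation (median -0.23, adjusted p = 0.000991; -0.43 in Huh1 and -0.12 in Huh7), within the middle 95% of random lists of matched brightness, and the heat shock response (median -0.43, adjusted p = 0.00902; -0.09 in Huh1 and -0.73 in Huh7) fell, with UQCRC2, a complex III subunit, at -0.84 ± 0.21 and HSPA8, a chaperone, at -1.49 ± 0.56. The heat shock list also held HSPB8, a small chaperone, at 2.43 ± 0.68. Ribosome biogenesis fell (median -0.26, adjusted p = 0.00277; 0.11 in Huh1 and -0.66 in Huh7), with NPM1, a nucleolar chaperone, at -0.93 ± 0.24. Mitosis fell (median -0.26, adjusted p = 0.0106; 0.05 in Huh1 and -0.73 in Huh7), with KIF20A, a mitotic kinesin, at -1.51 ± 0.47 and PTTG1, securin, at -1.40 ± 0.24. Metallothioneins and metal transporters fell (median -0.29, adjusted p = 0.0183; -0.44 in Huh1 and -0.24 in Huh7), and MT1F, which was below background on the Huh1 5-FU array, had -2.20 in Huh7. The 9 metallothioneins named for disulfiram had a median of -4.02 in Huh1, between different slides, and -0.95 in Huh7, within a slide. The list of pyrimidine and folate metabolism, which holds the target of 5-FU, had a median of -0.04 (adjusted p = 0.882).

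Of 14683 genes, 0 passed in limma between 5-FU and control (lowest adjusted p = 0.332), while 2053 had an unadjusted p below 0.05, 1025 higher and 1028 lower, against 734 expected by chance. Of 33 lists, 18 passed, 10 higher and 8 lower, and 0 passed with an estimated correlation (adjusted p between 0.837 and 0.904 for each list named as risen or fallen). The 5-FU and control arrays of Huh1 were on different slides and those of Huh7 on the same slide, so the Huh7 values are the within-slide ones. With the slide as a term the list of epithelial-mesenchymal transition had a median of -0.07.

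**Figure D2:**
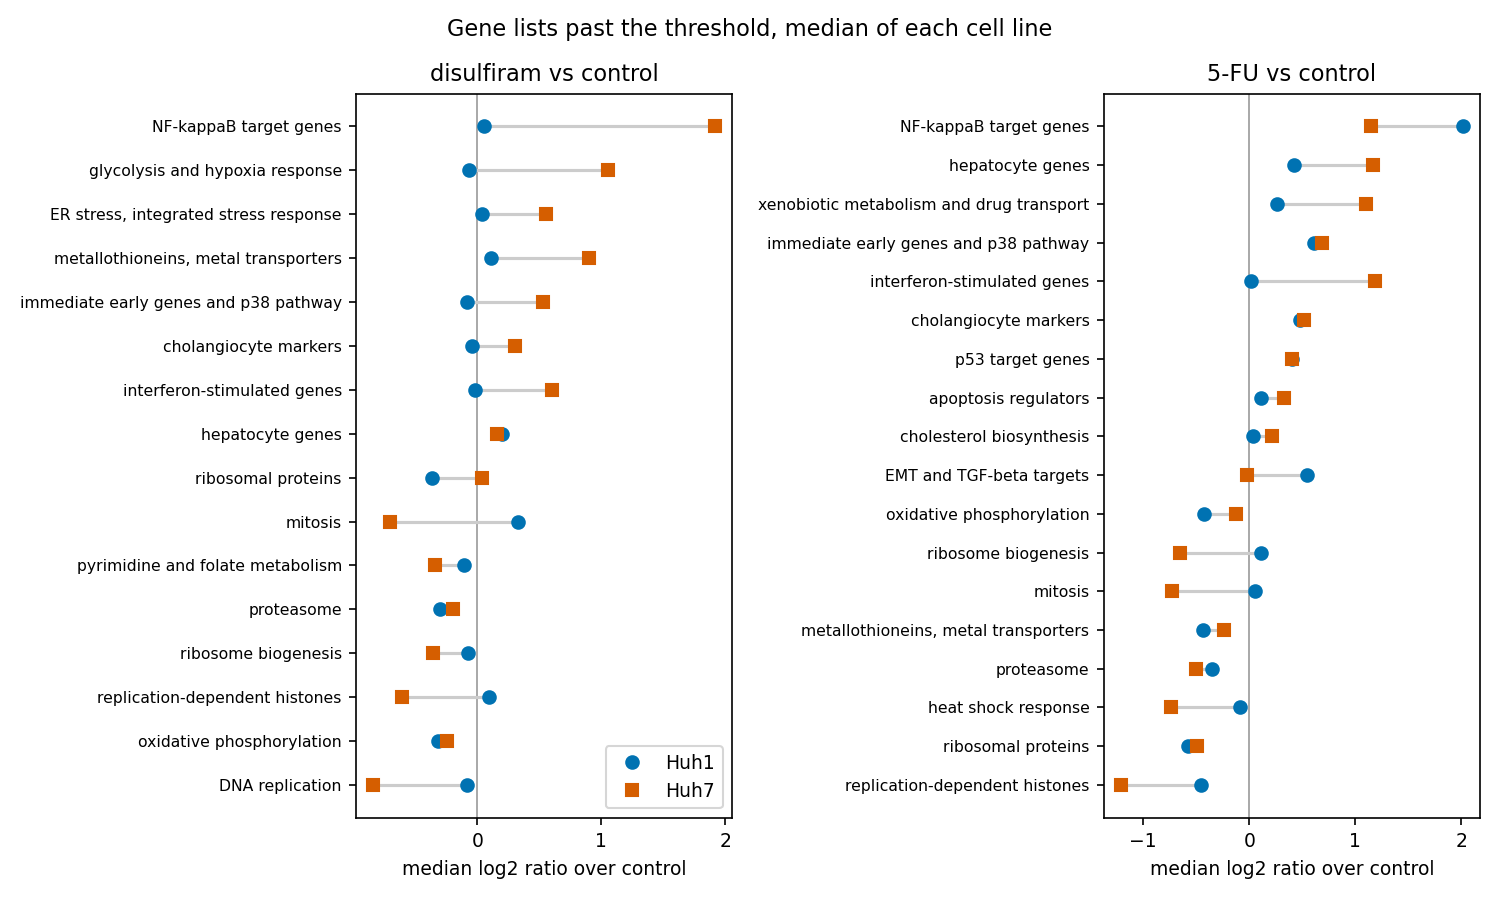
The median log2 ratio over control of each gene list that passed camera with a preset correlation, for disulfiram on the left and 5-FU on the right. Circles are Huh1, squares are Huh7, each from 1 pair of arrays, and grey lines join the lines of a list. NF-kappaB target genes had medians of 0.05 in Huh1 and 1.92 in Huh7 with disulfiram, and of 2.02 and 1.15 with 5-FU.

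The drugs were compared directly, at doses that differed (0.1 uM disulfiram and 1 uM 5-FU). The metallothioneins separated the drugs most: MT1G was at least 841-fold higher with disulfiram than with 5-FU, and MT1M had a log2 difference of 8.94 ± 1.02. These differences include lower levels with 5-FU than in controls (medians of -4.02 in Huh1 and -0.95 in Huh7 over 9 metallothioneins). Between the drugs 9 of 22 members of the list passed when adjusted over the list alone and 0 over all genes tested, and the list passed camera (median 0.21, adjusted p = 2.21e-05, and adjusted p = 0.843 with an estimated correlation, as for each list that passed between the drugs). DNA replication genes were lower with disulfiram than with 5-FU (median -0.52, adjusted p = 1.06e-08; -0.19 in Huh1 and -1.01 in Huh7), led by CCNE2, a cyclin of S phase entry, at -1.30 ± 0.57 and CLSPN, a checkpoint adaptor, at -1.27 ± 0.39. Ribosomal proteins (median 0.37, adjusted p = 1.91e-08) and replication-dependent histones (median 0.50, adjusted p = 4.76e-06) were higher with disulfiram, with RPL3 at 1.096 ± 0.22 and H1-2 at 1.46 ± 0.27. Much of the difference in ribosomal proteins was shared by genes as bright, whose random lists had a median of 0.27. Glycolysis and hypoxia genes were higher with disulfiram (median 0.42, adjusted p = 0.000512; 0.09 in Huh1 and 0.81 in Huh7), with PFKFB4, a regulator of glycolysis, at 1.55 ± 0.32. CA9 had 3.10 in Huh1 and -0.04 in Huh7.

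Hepatocyte genes were lower with disulfiram than with 5-FU (median -0.47, adjusted p = 6.54e-06, and adjusted p = 0.843 with an estimated correlation, as for the other lists here), with HPX at -2.14 ± 0.39 and VTN, vitronectin, at -2.05 ± 0.27. So were p53 target genes (median -0.42, adjusted p = 0.00068), with CDKN1A at -1.62 ± 0.69 and GDF15 at -2.54 in Huh1 and 0.11 in Huh7, and apoptosis regulators (median -0.22, adjusted p = 0.0027), with BCL2L1, a survival protein, at -1.03 ± 0.33 and TNFSF10, a death ligand, at -0.85 ± 0.63. NF-kappaB target genes were lower over both lines (median -0.58, adjusted p = 0.00867), with -1.57 in Huh1 and 0.50 in Huh7. SAA1, an acute phase protein of that list, had -4.18 and 1.42. Over both lines, pyrimidine and folate metabolism (median -0.21, adjusted p = 0.0138), xenobiotic metabolism (median -0.55, adjusted p = 0.0212, and -0.52 with genes below background at their bound), DNA repair (median -0.30, adjusted p = 0.022) and immediate early genes (median -0.26, adjusted p = 0.0319) were lower with disulfiram. The medians in Huh1 and Huh7 were -0.12 and -0.43 for pyrimidine and folate metabolism, 0.02 and -1.03 for xenobiotic metabolism, -0.01 and -0.52 for DNA repair and -0.45 and 0.11 for immediate early genes. RRM2, a ribonucleotide reductase subunit, had -1.07 ± 0.37, SULT2A1, a sulfotransferase, had -1.70 ± 0.31, EXO1, a repair nuclease, had -1.36 ± 0.36, and JUN had -1.26 ± 0.22. Fibroblast and stellate cell markers (median -0.98, adjusted p = 0.0371), with COL1A1, a collagen chain, at -1.99 ± 0.56, and interferon-stimulated genes (median -0.50, adjusted p = 0.0371), with OAS1, an antiviral enzyme, at -0.95 ± 0.53, were lower too, although the fibroblast list had 0.13 without the filter on dim probes. On 1 of the 2 disulfiram arrays SULT2A1 and COL1A1 were below background, so their sizes rest in part on levels at background. Stress response genes (median 0.18, adjusted p = 0.0441; -0.07 in Huh1 and 0.46 in Huh7) and the proteasome (median 0.14, adjusted p = 0.0441; 0.04 in Huh1 and 0.24 in Huh7), the latter within the middle 95% of random lists of matched brightness, were higher with disulfiram, with ASNS, asparagine synthetase, at 1.05 ± 0.30 and PSMB7, a core subunit, at 0.53 ± 0.24.

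Of 14683 genes, 0 passed in limma between the drugs (lowest adjusted p = 0.404), and 1379 had an unadjusted p below 0.05. Of 33 lists, 17 passed, 6 higher and 11 lower with disulfiram, and 0 passed with an estimated correlation (adjusted p = 0.843 for each). The call of 1 gene, MT1A, was gained with an intensity trend in the prior variance (adjusted p = 0.0476). With the slide as a term the median of NF-kappaB target genes was 0.09, and 11 lists passed without the Huh7 5-FU array.

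Across genes, which are not independent replicates, the disulfiram and 5-FU responses averaged over the lines had a Pearson r of 0.544 and a Spearman rho of 0.511. Both share the control arrays, and simulated unchanged groups gave an r of 0.501, with a covariance of 0.107 against 0.176 in the data. The r was 0.407 within Huh1 and 0.620 within Huh7. Responses of the lines, which share no array, had an r of 0.153 for disulfiram (rho 0.100) and 0.260 for 5-FU (rho 0.300). Between drugs and lines without a shared array the r was 0.065 for disulfiram in Huh1 against 5-FU in Huh7 and 0.161 for the reverse. In all 8 such correlations were computed, as sizes without a test.

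Huh7 and Huh1 were compared over the 3 treatments to describe the lines themselves. IGF2, a fetal growth factor, was higher in Huh7 by a log2 difference of 13.83 ± 0.50, with an SD of 0.15 over the 3 Huh7 arrays and 1.09 over the 3 Huh1 arrays, and GSTP1, a glutathione transferase, by 13.52 ± 0.17. Each of these 2 genes was above background on 1 of the 3 Huh1 arrays, so the sizes rest in part on levels at background. EFEMP1, an extracellular matrix protein, was at least 1479-fold higher in Huh7, UCHL1, a ubiquitin hydrolase, had 10.35 ± 0.17, and APOC2, an apolipoprotein, was at least 325-fold higher. NR0B1, an orphan nuclear receptor, was at least 2625-fold lower in Huh7, CD36, a fatty acid receptor, at least 405-fold lower, MSN, a membrane-cytoskeleton linker, at least 417-fold lower, and LGALS4, a galectin, had -10.17 ± 0.18. The alpha-fetoprotein gene AFP, a marker of fetal liver and liver cancer, was higher by 8.90 ± 0.18, the glypican gene GPC3 by 3.30 ± 0.18 and the albumin gene ALB by 2.18 ± 0.19.

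By list, NRF2 target genes, which handle oxidants and electrophiles, were lower in Huh7 (median -2.22, adjusted p = 2.51e-07, and adjusted p = 0.997 with an estimated correlation, as for each list that passed here), and 23 of 27 members passed over all genes and 24 when adjusted over the list alone. AKR1B10, an aldo-keto reductase, had -7.74 ± 0.22. Cholesterol biosynthesis (median 1.04, adjusted p = 0.000785), stress response genes of the endoplasmic reticulum (median 1.12, adjusted p = 0.00136), hepatocyte genes (median 1.31, adjusted p = 0.00889, and 1.27 with genes below background at their bound) and NF-kappaB target genes (median 1.15, adjusted p = 0.00928) were higher in Huh7. The median of NF-kappaB target genes between the lines was 0.90 in controls, 0.44 with 5-FU and 2.86 with disulfiram. MSMO1, a sterol oxidase, had 4.57 ± 0.25, SDF2L1, a chaperone of the endoplasmic reticulum, had 2.38 ± 0.21, and CXCL5, a chemokine, had 6.53 ± 0.22. Hepatocyte genes were mixed: CPS1, a urea cycle enzyme, had -7.95 ± 0.74, while ARG1, another urea cycle enzyme, was at least 89.8-fold higher. Immediate early genes were lower in Huh7 (median -1.16, adjusted p = 0.0026, and -0.98 with genes below background at their bound), with FOSL1, an AP-1 subunit, at -4.63 ± 0.51. FOSL1 was above background on 1 and CPS1 on 2 of the 3 Huh7 arrays.

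Between the lines 7124 of 14683 genes passed in limma, 3861 higher and 3263 lower in Huh7. Of 33 lists 6 passed, 4 higher and 2 lower, and 0 passed with an estimated correlation (adjusted p = 0.997 for each). Fewer genes passed with the slide as a term, where 2 of the 3 Huh1 arrays and none of the Huh7 arrays were on slide 1. That term leaves the line difference resting on the 5-FU arrays alone, 1 per line. The number of genes was 4038 without either disulfiram array.

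For 10 genes set in advance, levels or ratios are given whether or not they passed. EPCAM RNA lay above the array's 75th percentile of probes on all 6 arrays, although the labels call the cells negative for the protein, which was not measured. It was at 1.60 in Huh1 control, 0.26 in Huh1 5-FU, 0.86 in Huh1 disulfiram, 1.36 in Huh7 control, 2.15 in Huh7 5-FU and 1.72 in Huh7 disulfiram. CDKN1A was at -1.20 in Huh1 control, 0.31 with 5-FU and -1.68 with disulfiram, and at -4.98, -1.48 and -2.73 in the same order in Huh7. MKI67, a marker of cycling cells, was at -0.42 in Huh1 control, -0.18 with 5-FU and 0.41 with disulfiram, and at 0.12, -0.13 and -0.74 in Huh7. TYMS, which encodes the target of 5-FU, had a log2 ratio of 5-FU over control of 0.21 ± 0.22 (adjusted p = 0.672) and of disulfiram over control of -0.29 ± 0.22 (adjusted p = 0.906). MAPK14, the p38 kinase, had -0.53 ± 0.19 with 5-FU (adjusted p = 0.348) and -0.21 ± 0.19 with disulfiram. ALDH1A1 and ALDH2, aldehyde dehydrogenases, had -0.40 ± 0.21 and -0.12 ± 0.23 with disulfiram (adjusted p = 0.906 and 0.945), and ALDH2 had 0.01 with loess between arrays. With disulfiram AFP had -0.04 ± 0.21, GPC3 had -0.33 ± 0.22 and ALB had -0.28 ± 0.23, and with 5-FU they had 0.12 ± 0.21, -0.21 ± 0.22 and 0.11 ± 0.23. The sign of AFP turned with loess for disulfiram (0.11), and those of AFP (-0.004) and ALB (-0.015) turned with median centring for 5-FU. None of these 10 genes passed in a drug comparison over all genes tested.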

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

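The tests of the slide, of the order of the arrays for the metallothioneins, of the Huh7 control array, of loess between arrays and of rotations for the numbers of lists were chosen after the results had been seen. The effects planted for the rotations also came after. Those of SLC30A1 and of rotations for the metallothioneins were set before their results. Values in parentheses are Huh1 and Huh7, and the number before them is the Huh7 value minus the Huh1 value.

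The lines moved in opposite directions, each beyond the spot noise (0.13), in 13 results among the lists past the threshold, their 2 leading members and the 10 genes given in every array, leaving out genes below background in a whole group, and with 1 array per line and treatment these differences were not tested. With disulfiram they were the mitosis list, -1.03 (0.33 and -0.70), EPCAM, 1.1 (-0.74 and 0.36), CDKN1A, 2.73 (-0.49 and 2.25), MKI67, -1.70 (0.84 and -0.86), and ENO2, 4.22 (-0.25 and 3.97). With 5-FU they were EPCAM, 2.13 (-1.34 and 0.79), ALB, 0.50 (-0.14 and 0.36), MKI67, -0.49 (0.24 and -0.25), and TGFB2, -5.58 (5.01 and -0.58), which was below background in Huh1 control. Between the drugs they were the list of NF-kappaB target genes, 2.07 (-1.57 and 0.50), EPCAM, -1.03 (0.60 and -0.43), MKI67, -1.20 (0.59 and -0.61), and SAA1, 5.60 (-4.18 and 1.42).

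The metallothioneins were higher with disulfiram in both lines. Brightness-dependent scaling was argued against, since the median of the 9 genes was 4.96 and with loess 5.08, where the 9 genes still passed over the list alone; a slide difference was also argued against, since both arrays of a line shared a slide and the smaller line median was 4.42. A single transcript read by all 9 probes was argued against. Of the 36 pairs of probes, 8, each with MT1F, ordered the control arrays of the lines in opposite ways beyond the spot noise (0.13). The rule set before asked that the zinc exporter SLC30A1 move the same way in both lines beyond the spot noise, and it was met. A condition on the standard error, not part of that rule, was not met (0.80 with a standard error of 0.69). Cross-hybridization among some of the copies therefore cannot be told apart from separate changes. Differences between arrays or cultures with no drug effect were not excluded, as each line and treatment had 1 array. Of 100 rotations 5 gave as many calls (9). With 5 added to the measured disulfiram values of these genes 7 did, so this decides nothing. A response of these genes to disulfiram may be the biological explanation, and repeated cultures would test it.

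Under 5-FU most lists of dim genes were higher and most lists of bright genes lower; by mean level cholesterol biosynthesis (2.24) and hepatocyte genes (1.54) were exceptions that were higher, and the metallothionein list (0.37) one that was lower. Scaling by brightness was argued against as the whole source, since 17 of the 18 lists stayed past the threshold in the same direction with loess, and a slide difference of the Huh1 5-FU array was argued against as the whole source, since 16 of the 18 kept their direction in Huh7, on 1 slide, beyond the spot noise (0.13). The slide as a term is no separate check. Huh1 5-FU was the only Huh1 array on slide 2, so the term takes it out of the drug comparisons. Differences between arrays with no drug effect stay open for the number of lists, since the rotations decide nothing: 14 of 100 gave at least 18, but 66 gave as many with a planted drug effect. The median over the rotations of the measured data was 13 lists (5 to 22). The 5-FU treatment itself may be the source and is untested beyond this.

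With disulfiram 12 of the 16 lists past the threshold shifted further in Huh7 than in Huh1. A Huh7 control array that stands apart was argued against as the whole source, since 4 of these 12 did not shift the same way in Huh7 5-FU against that control. DNA replication, among these 4, also differed between the drug arrays of Huh7, where no control enters (-1.01). This holds only if 5-FU did not move these 4 lists the other way, which was not excluded. For the other 8 of the 12 the control array and a drug effect cannot be told apart, because 5-FU shifted them the same way against the same array. Differences between arrays with no drug effect stay open for the number of lists, since the rotations decide nothing: 38 of 100 gave at least 16, but 62 gave as many with a planted drug effect. The median over the rotations of the measured data was 14 lists (7 to 21). A line-specific response to disulfiram may remain and was not tested.

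For the genes between Huh7 and Huh1, the 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split, 1 of the 10, gave 7124 genes, and the highest of the others gave 0.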

How the results depend on the processing

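Loess between arrays and the test of each probe were chosen after seeing the data, and the other alternatives were set before. The number of genes past the threshold in limma was 0 for each drug against control under all settings run (576 for disulfiram and 2053 for 5-FU at an unadjusted p below 0.05, as reported), and 0 between the drugs except for 1 gene with an intensity trend in the prior variance. Between Huh7 and Huh1 it lay between 5897 and 10511 (each probe tested), except for 3081 with the slide as a term, which takes up part of the line difference, and 4038 to 5442 with an array left out. Leaving out an array assumes that a lone array varies like the others. Where a value changed, the cause was not tested unless given.

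With camera and an estimated correlation 0 lists passed in every comparison. The 2 residual degrees of freedom left that form almost unable to pass a list, even between Huh7 and Huh1, where 7124 genes passed in limma. Of the 16 lists past the threshold for disulfiram against control, 8 stayed past it in the same direction with quantile normalization and 8 with loess. With loess 7 of the others fell short and 1, ribosomal proteins, turned sign. For disulfiram against control, 16 lists became 10 with quantile normalization, 10 with loess and 7 to 20 with an array left out, the lowest without the Huh7 control. With the cell line block left out of the fit, 15 lists passed for disulfiram, 18 for 5-FU and 11 rather than 17 between the drugs, where leaving out an array gave 11 to 18. For 5-FU the other settings gave 13 to 19 lists. The correlation across genes of the drug responses (0.544) was 0.463 with normexp, 0.516 with quantile normalization, 0.524 without a filter, 0.48 with the filter on all 6 arrays and 0.522 with loess. That of the disulfiram responses in the lines (0.153) was 0.170 with normexp, 0.125 with quantile normalization, 0.100 without a filter and 0.122 with loess. That of the 5-FU responses (0.260) was 0.161 without a filter and 0.340 with the filter on all 6 arrays.

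The sign turned in these cases. With the slide as a term, 5-FU against control gave AFP -0.055, EPCAM 0.52, MKI67 0.175 and the epithelial-mesenchymal list -0.066. With that term disulfiram against 5-FU gave AFP 0.02, ALDH2 -0.12, CA9 -0.11, EPCAM -0.708, NF-kappaB target genes 0.093 and SAA1 0.37, and Huh7 against Huh1 gave MKI67 0.047. This MKI67 value is the ratio of the 5-FU arrays alone. With loess, disulfiram against control gave AFP 0.11, ALDH2 0.014, MKI67 0.022 and ribosomal proteins 0.044, and 5-FU against control gave ALDH2 0.003 and MKI67 0.039. With normexp, MKI67 was 0.026 for disulfiram against control and 0.056 between the drugs, and ALDH1A1 was 0.022 between the drugs. Between the drugs ALDH1A1 was 0.025 with the mean over probes, and fibroblast markers were 0.13 without a filter. With median centring AFP was -0.004 and ALB -0.015 for 5-FU.

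Leaving out 1 array or 1 line turned the sign of further values, given here as log2 ranges. For disulfiram against control the lists were NF-kappaB target genes -0.067 to 1.98, cholangiocyte markers -0.042 to 0.44, glycolysis and hypoxia -0.064 to 1.05, immediate early genes -0.084 to 0.68, interferon-stimulated genes -0.14 to 0.80, mitosis -0.70 to 0.33, replication-dependent histones -0.61 to 0.12, ribosomal proteins -0.36 to 0.035 and ribosome biogenesis -0.58 to 0.061. The genes were AFP -0.18 to 0.105, ALDH2 -0.33 to 0.087, CDKN1A -0.49 to 2.25, ENO2 -0.25 to 3.97, EPCAM -0.999 to 0.62, H3C10 -0.96 to 0.038, ISG20 -0.008 to 2.12, KLF4 -0.045 to 2.81, MKI67 -0.86 to 0.84 and PLK1 -0.95 to 0.025. For 5-FU against control the lists were the epithelial-mesenchymal list -0.066 to 0.54, mitosis -0.85 to 0.28 and ribosome biogenesis -0.66 to 0.11. The genes were AFP -0.091 to 0.33, ALB -0.14 to 0.36, ALDH2 -0.45 to 0.073, EPCAM -1.34 to 0.79, MKI67 -0.55 to 0.54 and TGFB2 -0.58 to 5.01. The chloride channel CFTR had fitted values of -0.66 to 4.47, but it was below background in both controls and on the Huh1 5-FU array, so these measure no direction in Huh1. For disulfiram against 5-FU the lists were DNA repair -0.56 to 0.076, NF-kappaB target genes -1.57 to 0.50, endoplasmic reticulum stress -0.067 to 0.56, immediate early genes -0.54 to 0.11 and xenobiotic metabolism -1.14 to 0.033. The genes were AFP -0.33 to 0.02, ALDH1A1 -0.21 to 0.14, ALDH2 -0.12 to 0.24, CA9 -0.11 to 3.17, EPCAM -0.71 to 0.88, GDF15 -2.54 to 0.11, GPC3 -0.33 to 0.085, MKI67 -0.73 to 0.72, SAA1 -4.18 to 1.42 and TNFSF10 -1.79 to 0.089. For Huh7 against Huh1 it was MKI67 -0.56 to 0.29.

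Signal over background limits the dim genes: with the filter on all 6 arrays fewer of the named genes were tested, and folds against groups below background are lower bounds.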

Other observations

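Several lists fixed before the data were examined missed the threshold and were not described above. With disulfiram the heat shock response had a median of -0.23 (limma camera adjusted p = 0.0579), with a mean of 0.07 on the other side of 0, xenobiotic metabolism and drug transport had 0.14 (adjusted p = 0.0581, and 0.10 with genes below background at their bound) and Wnt target genes had -0.21 (adjusted p = 0.0728). NRF2 target genes had -0.05 with disulfiram (adjusted p = 0.556) and -0.24 with 5-FU (adjusted p = 0.05003), antioxidant enzymes had -0.12 and -0.05, and autophagy and lysosome genes had -0.06 and 0.03. Fatty acid and lipid metabolism had -0.14 with disulfiram and -0.08 with 5-FU. Markers of leukocytes, which a pure cell line should lack, had a mean level of -2.74 in the disulfiram and control arrays and medians of 0.20 with disulfiram and 0.28 with 5-FU. With genes below background at their bound, or left out where none could be had, these were 0.12 over 15 of 19 members and 0.11 over 16.

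Dim and bright genes behaved differently in all drug arrays. Across genes, the Spearman correlation of the ratio over control with the level was -0.262 in Huh1 and -0.217 in Huh7 for disulfiram, and -0.108 and -0.203 for 5-FU. The interquartile range of gene levels was 4.61 in Huh1 control, 4.49 with 5-FU and 4.40 with disulfiram, and 4.38, 4.13 and 4.12 in Huh7. Of the lists past the threshold, 12 of 16 for disulfiram, 17 of 18 for 5-FU and 16 of 17 between the drugs lay outside the middle 95% of random lists of matched brightness. Those within it were the proteasome, pyrimidine and folate metabolism, ribosomal proteins and mitosis for disulfiram, oxidative phosphorylation for 5-FU and the proteasome between the drugs. EPCAM RNA was above the array's 75th percentile on each of the 6 arrays, in cells labelled as negative for the protein.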
